A study of Mus musculus with 3 samples.

How the data were processed

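The series holds 3 DamID samples of mouse haemogenic endothelium made from embryonic stem cells. In DamID a bacterial DNA adenine methyltransferase (DAM) is fused to a protein of interest and methylates DNA near the places where that protein sits, and DAM alone, unfused, gives the background. Per the labels, GFI1:DAM, GFI1B:DAM or DAM alone was placed under doxycycline control at the Hprt docking site of AinV18 embryonic stem cells. FLK1-positive cells were taken from embryoid bodies at day 3.25, and TIE-2 and c-KIT haemogenic endothelium was sorted on day 2 of culture. DNA was cut with DpnI, which cuts methylated sites, amplified and sequenced on an Illumina HiSeq. Each fusion and the control is represented by 1 sample, which per the labels stands for 2 biological replicates together. No replicate can be told apart in the files, so no value carries an SD, and no test across replicates was possible.

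The data analysed are the authors' 2 gene lists, one per fusion, with gene, biotype, intervals, read number and reads per kb. Each list was assigned to its fusion from the name of its worksheet. No values of the DAM control were used here. Per the file headers of the GFI1B list, the authors ran BayesPeak and a second method written SS at a threshold of 0.05, merged the lanes of a sample and subtracted control reads before SS. The header of the GFI1 list stops after naming BayesPeak, so its threshold and whether control reads were subtracted are not given in the sources used here, and nor is the aligner. The genome build is mm9 per the submitters' processing notes. The deposited read number per gene was treated as a score, since it may be net of control reads and the headers do not say. The deposited signal is reads per kb of interval, computed by the authors from that read number and the summed interval length without any scaling to library size. Recomputing it gave the deposited value within 0.0051 in all 5238 rows of the GFI1 list and all 5327 rows of the GFI1B list. Library depth is unknown, so reads per kb were used only to describe and rank genes inside a list, and the same value in both lists is not the same occupancy. How intervals were assigned to genes, and at what distance, is not given in the sources used here.

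Gene symbols were matched to a RefSeq table of 49997 mouse genes, 21900 of them protein-coding, made on assembly GRCm38.p6. Because that build differs from mm9 the table supplied only names, biotypes and gene lengths, and every coordinate comes from the deposited lists. Of the rows, 4633 (88.4%) of the GFI1 list and 4745 (89.1%) of the GFI1B list matched, giving 4618 and 4726 distinct genes.

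The comparisons, the named genes and 19 gene lists were fixed before the data were examined. Some genes are members of several lists, so results of different lists are not independent. Sharing of genes was tested with Fisher's exact test, two-sided, over all genes of the table. Sharing of intervals (overlap of at least 1 bp) was compared with 1000 random placements on the same chromosome. Each gene list was tested for GFI1, for GFI1B and for genes listed for both with Fisher's exact test against all other genes, with Benjamini-Hochberg adjustment over the 57 tests. Alternatives fixed at the same time were a background of protein-coding genes, 10000 random lists matched on gene length in 50 bins, and the stronger 50% of each list. Random lists matched on both length and class (protein-coding or other) were added after the data were seen. The difference between the fusions within a list was tested with the exact McNemar test. The rank relation used 100000 permutations. All these tests treat genes or intervals as the units, which are not independent replicates. No files here give the distance between interval and gene or an mm9 annotation, so the planned comparison of location was made over the authors' gene biotypes.

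The rule for named genes took the 10 strongest genes of each list, up to 4 members of each fixed list per fusion, the 5 genes with the most intervals and 12 genes chosen by name, 141 in all. The values of 1 fixed list and of 1 named gene are not reported here, and both stay in the counts of lists and genes. The rule asked for a fold, score or p first. With none of these as a column, the authors' sorting value, reads per kb, was used.

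The steps were tested on simulated data. Lists of genes were drawn from the 49997 genes at the GFI1 listing rates of their length and class, with the odds of the 27 myeloid genes raised 6 times. Over 40 runs, the random lists matched on length and class called that list in 60.0% of runs. They called the other 18 lists in 0.278% of cases. The number of random lists drawn per simulated run is not given here. Fewer lists than were drawn for the data would raise the smallest p they can give. Both rates could then be lower than those of the test applied to the data. Genes were drawn independently and within the same bins that these random lists use, so a low rate follows from the setting. It does not show the rate where neighbouring genes share intervals or other factors act. Fisher's exact test against all genes called the myeloid list in 90.0% of runs. But that test also called the other 18 lists in 48.9% of cases, since these hold long protein-coding genes. The report therefore gives the values of matched lists beside the counts for GFI1 and for GFI1B. With 40.0% of 7595 simulated intervals made identical, 41.4% were found to overlap, and with none made identical, 0.698%. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.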

Results

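GFI1 and GFI1B are zinc-finger transcriptional repressors, and the series asked where they sit in haemogenic endothelium, the endothelial cells from which blood emerges, and with which link to the histone demethylase LSD1. Genes marked by GFI1:DAM and by GFI1B:DAM were available as 1 deposited list each. Reads of a control were subtracted for the GFI1B list per its header, and whether this was done for the GFI1 list is not given. Every value is a single pooled measurement of 2 biological replicates, with no error between replicates. Library depth is unknown. The deposited reads per kb of interval rank genes within a list and are not scaled between lists.

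Both fusions marked a large set of genes, most of them at a single place. The GFI1 list held 5238 genes at 7166 distinct intervals, and the GFI1B list 5327 genes at 7595 distinct intervals. A single interval was listed for 3929 (75.01%) of the GFI1 genes and 3832 (71.9%) of the GFI1B genes. Median interval width was 1201 bp for GFI1 (interquartile range 851 to 1701 bp) and 1351 bp for GFI1B (951 to 1851 bp). Median reads per kb were 48.7 and 53.6. Bach2, which encodes a transcriptional repressor of lymphoid cells, carried 11 intervals for GFI1 and 12 for GFI1B, of which 9 and 12 were listed under no other gene. The read-through locus Gm20388 had the most, 20 and 19, spread over 4194 and 4240 kb, with 14 and 11 listed under no other gene. Fgfr2, an FGF receptor gene of 104 kb, was listed with 13 and 16 intervals over 2725 and 2878 kb, and 6 and 4 of them were listed under no other gene. The strongest gene by reads per kb in both lists was the pseudogene AY036118 on chromosome 17 (mm9 39983347 to 39985147 for GFI1, with a further interval at 39975997 to 39977497), at 4140 reads per kb for GFI1 and 5622 for GFI1B. How reads of repeated sequence were handled there is not given in the sources used here. Behind it stood Zfml at 382 reads per kb and 2010107H07Rik at 359 in the GFI1 list. In the GFI1B list 2010300F17Rik followed at 2426 reads per kb and 1810011O10Rik at 995, neither of them listed for GFI1. The intervals of these last 2 genes, and the GFI1 interval of 2010107H07Rik, were listed under a further gene as well.

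The genes that name the populations and proteins of the study were split between listed and not listed. Gfi1, Gfi1b and Kit, the gene of the c-KIT receptor used in the sort, were in neither list, which does not show that they were unbound. Runx1, the transcription factor required for blood emergence, was listed for both fusions, at 57.0 reads per kb for GFI1 and 81.3 for GFI1B. Its GFI1 intervals lay on chromosome 16 at 92627355 to 92628255 and at 92715555 to 92716355 (mm9), and both overlapped GFI1B intervals. Kdr, which encodes the VEGF receptor FLK1, stood at 70.2 reads per kb for GFI1 and 70.4 for GFI1B, with intervals at 76357782 to 76358782 and 76365782 to 76369382 on chromosome 5 for GFI1. Both overlapped GFI1B intervals, and GFI1B had another at 76383732 to 76384682. Tek, the gene of TIE-2, stood at 61.8 and 57.3 reads per kb, and Pecam1, an endothelial adhesion molecule, at 67.9 and 50.4. Sox7, an endothelial SOXF factor, had nearly the same interval in both lists, from 64576963 on chromosome 14 to 64578613 for GFI1 and to 64578563 for GFI1B. Sox17, another SOXF gene (92.7 reads per kb, chromosome 1, 4486234 to 4487884), and Cdh5, the VE-cadherin gene (39.2 reads per kb), were listed for GFI1B and not for GFI1. Kdm1a, which encodes LSD1 itself, was listed at 39.2 reads per kb for GFI1 and 43.9 for GFI1B, both below the list's median. Rcor1, which encodes the CoREST scaffold, was listed for GFI1 at 46.2 reads per kb and not for GFI1B. Exon and intron positions are not given, since no annotation of mm9 was used here.

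**Figure D1:**
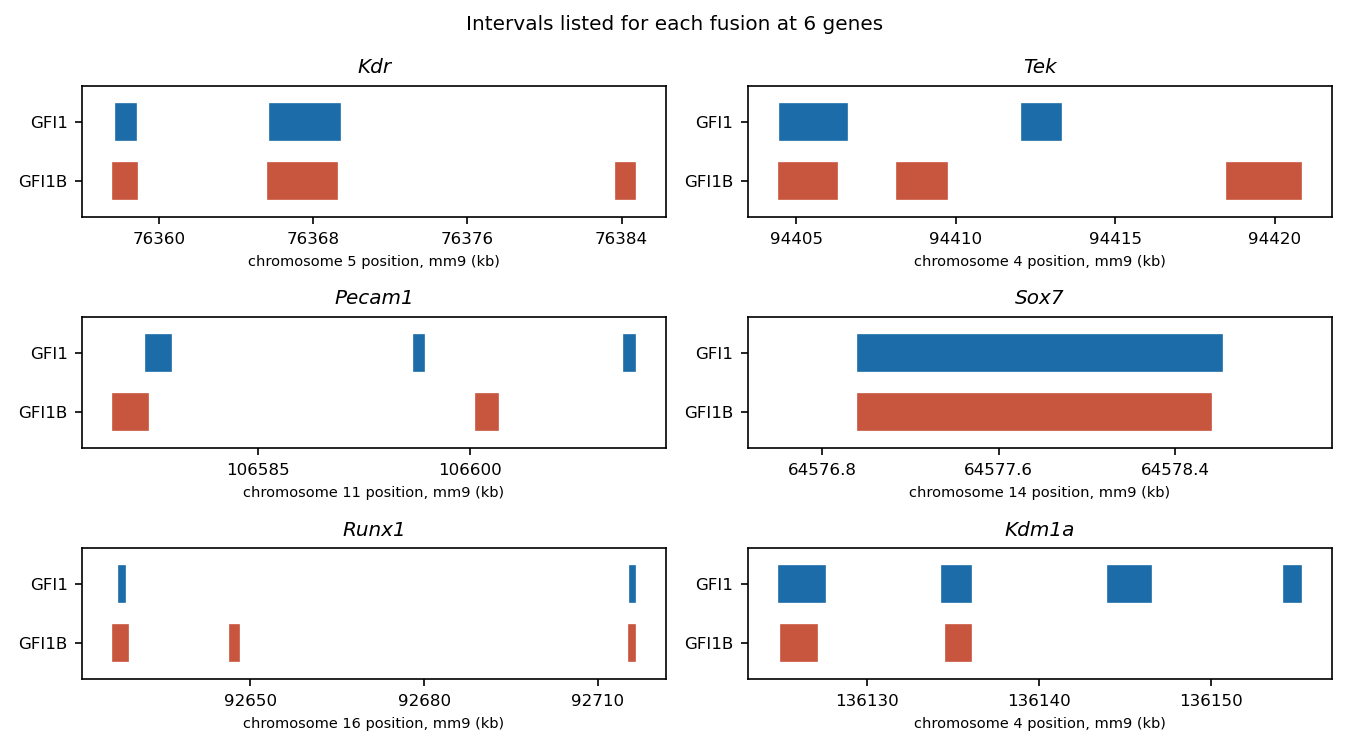
Intervals listed for GFI1 (blue) and GFI1B (red) at 6 genes, drawn to scale along mm9 chromosome position in kb, with each panel on its own scale. Every panel has at least 1 interval of each fusion overlapping the other, and at Kdr a further GFI1B interval runs from 76383732 to 76384682.

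The first comparison asked how far the fusions marked the same genes and places. Of the genes matched to RefSeq, 2660 were listed for both, which is 57.6% of the GFI1 genes and 56.3% of the GFI1B genes. Independent lists of these sizes would share 437 of 49997 genes, so the overlap was 6.09-fold higher, with an odds ratio of 28.5 (95% confidence interval 26.5 to 30.7, Fisher's exact test, two-sided). Among protein-coding genes alone the overlap was 3.13-fold higher and the odds ratio was 13.4. Both expectations take every gene as equally likely to be listed, whereas both lists favoured long genes, as shown next. Part of this excess therefore comes from gene length, and no length-matched expectation was computed. By the deposited Ensembl identifiers 2953 genes were shared, and 2288 of these (77.5%) had an interval of their GFI1 entry overlapping an interval of their GFI1B entry. By position, 2808 of 7166 GFI1 intervals (39.2%) overlapped a GFI1B interval, against a mean of 63.3 over 1000 random placements. The permutation p, one-sided, was 0.000999, the smallest that 1000 placements can give. When each interval was instead moved 5 to 50 kb along its own chromosome, which keeps the neighbourhood, 210 overlapped on average and the excess was 13.4-fold. Across the 2660 shared genes, which are not independent replicates, reads per kb of the fusions were related with Spearman's rho 0.518 and, on the log2 scale, Pearson's r 0.540 (permutation p 1e-05 for each, two-sided, the smallest that 100000 resamples can give). Part of the overlap and of the rank relation may come from DAM itself. This could act through a control shared by the lists or through DAM marks left in a list without subtraction. With no library counts this part could not be simulated.

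Long genes were listed far more often than short ones. Of the protein-coding genes in decile 1 of length (median 0.942 kb) 3.61% were listed for GFI1 and 2.60% for GFI1B, and of those in decile 10 (median 185 kb) 51.3% and 50.5%. Counts of gene lists against all genes are therefore given with the count of random lists of the same gene lengths and the same share of protein-coding genes, called matched lists from here on.

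**Figure D2:**
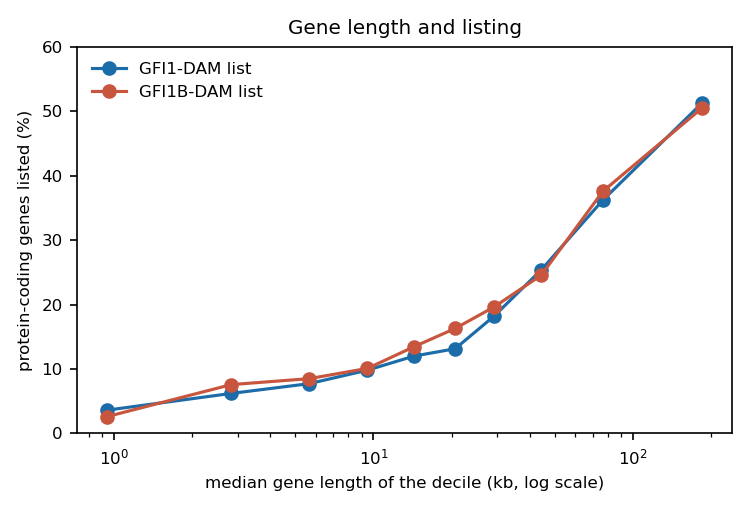
Share of protein-coding genes listed for GFI1 (blue) and GFI1B (red) on the vertical axis in percent, by decile of gene length, with the median length of each decile in kb on a log axis. Listing climbs from 3.61% and 2.60% in the shortest decile to 51.3% and 50.5% in the longest.

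Endothelial identity genes were listed more often than other genes for both fusions. Of 39 such genes 19 were listed for GFI1, 26 for GFI1B and 17 for both, where matched lists gave 8.75, 9.18 and 5.53. Odds ratios against all genes were 9.37 for GFI1 (Fisher's exact test, adjusted p 8.46e-10) and 19.3 for GFI1B (adjusted p 7.33e-17). The permutation p against matched lists, adjusted, was 0.00228 for GFI1 and 0.00142 for GFI1B. Besides Kdr, Tek, Pecam1 and Sox7 they included Ptprb, the gene of the vascular endothelial phosphatase VE-PTP (79.5 reads per kb for GFI1, 190 for GFI1B), Eng, the TGF-beta co-receptor endoglin (88.6 and 81.4), and Tal1, a regulator of blood and endothelial fate (155 and 67.1). Procr, the protein C receptor gene (109 reads per kb), was listed for GFI1B and not for GFI1.

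Genes of TGF-beta and BMP signalling, and of VEGF, PDGF and FGF signalling, were also listed in excess for both fusions. For TGF-beta and BMP 21 of 36 genes were listed for GFI1 and 22 for GFI1B, against 10.1 and 10.3 in matched lists (permutation adjusted p 0.00163 for both). They included Smad7 (103 reads per kb for GFI1, 117 for GFI1B), Smad6 (78.5 and 71.8) and the decoy receptor gene Bambi (113 and 99.5), but the listed members had medians of 46.9 and 43.8, below the medians of all listed genes. For VEGF, PDGF and FGF 16 of 34 genes were listed for GFI1 and 18 for GFI1B, against 8.67 and 8.80 in matched lists (permutation adjusted p 0.0157 and 0.00163). Kdr was listed for both, and so was Fgfr2, with the spread of intervals given above. Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, was listed for GFI1 (69.1 reads per kb) and not for GFI1B, and the ephrin receptor gene Epha2 for GFI1B (98.4) and not for GFI1.

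Adhesion, junction and EMT genes were listed 30 of 46 times for each fusion and 23 times for both. Matched lists gave 15.1 for GFI1 and 15.3 for GFI1B (permutation adjusted p 0.00142 for both). Vim, the intermediate filament gene of mesenchymal cells, stood at 172 reads per kb for GFI1 and 160 for GFI1B. Zeb1, which encodes a repressor of E-cadherin that drives EMT, was listed for GFI1 (151) by an interval it shared with another gene and not for GFI1B, while the polarity gene Pard3 stood at 63.8 for GFI1 and 223 for GFI1B. Of 39 cell cycle genes 15 were listed for each fusion, against 5.78 and 6.18 (permutation adjusted p 0.00142 and 0.00268), among them Ccnd3 (99.0 and 134), Myc (71.2 and 94.2) and Aurkb (99.9 and 79.4).

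Cardiac and smooth muscle genes, a fate that mesoderm can take beside endothelium, passed for GFI1B in every test, and for GFI1 in all but the matched lists. Of 32 genes 17 were listed for GFI1B against 7.35 in matched lists (permutation adjusted p 0.00317), and 12 for GFI1 against 7.25 (permutation adjusted p 0.129). For GFI1 the list passed against all genes (Fisher's exact test, adjusted p 3.10e-05), against protein-coding genes (0.0219) and against lists matched on length alone (permutation adjusted p 0.0149). The fusions were not shown to differ here, with 1 gene listed for GFI1 alone and 6 for GFI1B alone (exact McNemar p 0.125, adjusted p 1). Tbx20, a cardiac T-box gene, had a GFI1B interval of 9901 bp on chromosome 9 (24571998 to 24581898) at 140 reads per kb, and stood at 104 for GFI1. Tpm1 (79.9 and 85.2) and Cald1 (66.3 and 84.0) were listed for both, and Ttn for GFI1B (108) and not for GFI1.

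Haematopoietic transcription factor genes were listed 13 of 36 times for GFI1, 15 for GFI1B and 12 for both. Against all genes each count passed (Fisher's exact test, adjusted p 2.30e-05, 9.65e-07 and 5.69e-07). Against matched lists the count for both passed (6.22 in matched lists, permutation adjusted p 0.0372), and those for GFI1 (9.27, adjusted p 0.335) and for GFI1B (9.60, adjusted p 0.0991) did not. With lists matched on length alone GFI1B passed too (permutation adjusted p 0.0152). The members included Runx1, Tal1, Fli1 (55.0 reads per kb for GFI1, 65.2 for GFI1B), Meis1 (59.6 and 66.5) and Erg (47.9 and 85.9). Of these, Tal1, Fli1 and Erg are also members of the endothelial list and were listed for both fusions. The count for both is therefore not separate from the endothelial result. Hhex, a homeobox gene of blood and endothelial progenitors, was listed for GFI1B at 228 reads per kb and not for GFI1.

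Erythroid, myeloid and megakaryocyte genes did not pass in any test for either fusion. Erythroid genes were listed 3 of 27 times for GFI1 and 2 for GFI1B, myeloid genes 2 of 27 times for each, and megakaryocyte genes 3 of 21 times for each with none shared. Matched lists gave 3.43 and 3.65 erythroid, 3.21 and 3.58 myeloid, and 2.77 and 3.07 megakaryocyte genes. Adjusted p against all genes was 0.505 or higher (Fisher's exact test). Among haematopoietic surface and signalling genes 8 of 28 were listed for GFI1, which passed against all genes (odds ratio 3.94, Fisher's exact test, adjusted p 0.00506), and 5 for GFI1B, which did not (adjusted p 0.215). Matched lists gave 5.27 and 5.68 (permutation adjusted p 0.448 and 1). Cd34 (44.7 and 53.0 reads per kb) and Ptprc, the gene of the pan-leukocyte antigen CD45 (45.3 and 68.8), were listed for both, and Vav1 for GFI1B (137) and not for GFI1.

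The genes of the LSD1 and corepressor complexes passed against all genes, with 8 of 24 for GFI1 (Fisher's exact test, adjusted p 0.00172) and 9 for GFI1B (0.000425), but not against matched lists (6.36 and 6.44, permutation adjusted p 0.759 and 0.494). Besides Kdm1a and Rcor1 they included Hdac2 (84.5 reads per kb) in the GFI1B list. Of the 9 members listed for GFI1B 3 had no interval of their own, among them Sin3a (88.2). Other lists gave the same pattern for 1 or both fusions. Arterial and Notch genes were listed 6 of 27 times for GFI1 and 9 for GFI1B, against 5.07 and 5.35 in matched lists, with Notch2 (65.7 and 77.8) in both. Venous and lymphatic genes were listed 6 and 5 of 14 times, against 3.68 and 3.85, with Nrp2 (55.6 and 102) in both. Wnt signalling genes were listed 12 and 10 of 44 times, against 9.83 and 10.2, with Fzd2 (84.6 and 87.7) in both. Pluripotency genes were listed 5 and 7 of 22 times, against 2.57 and 2.80, with Sall4 (82.7 and 83.9) in both and Pou5f1 (76.2) for GFI1B alone. No permutation adjusted p of these counts against matched lists was below 0.0524. With lists matched on length alone, arterial and Notch genes (permutation adjusted p 0.0375) and pluripotency genes (0.00665) passed for GFI1B.

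The comparison lists behaved unlike each other. Long neuronal and synaptic genes, not expected to be expressed in these cells, were listed 26 of 36 times for GFI1 and 22 for GFI1B, but matched lists gave 21.9 and 20.0 (permutation adjusted p 0.359 and 0.785). Ribosomal protein genes, which are short and active in every cell, were listed 11 and 13 of 50 times against 3.23 and 3.84 (permutation adjusted p 0.00163 and 0.00142). Against protein-coding genes of any length the ribosomal counts did not pass (Fisher's exact test, adjusted p 0.556 and 0.293). In all, 15 of the 19 lists passed for each fusion against all genes, 9 against protein-coding genes, and 7 for GFI1 and 8 for GFI1B against matched lists.

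**Figure D3:**
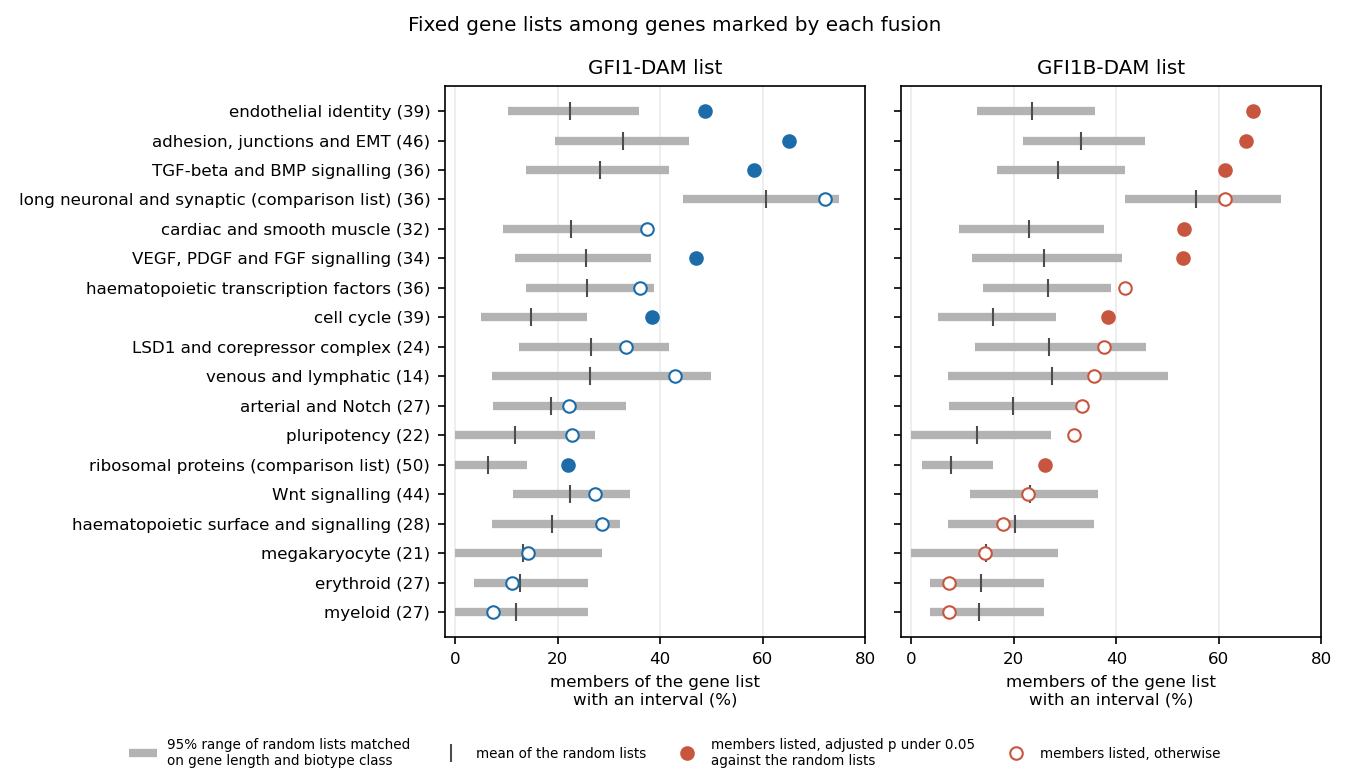
Members of 18 fixed gene lists with a listed interval, in percent on the horizontal axis, for GFI1 (left) and GFI1B (right), with the number of members in brackets. Grey bars are the 95% range and ticks the mean of 10000 random lists matched on gene length and class, and filled circles passed against them. Endothelial genes stand at 48.7% and 66.7%, and long neuronal genes at 72.2% and 61.1%, the latter inside their grey bars.

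The last comparison asked whether the fusions differed. No fixed list was listed more often for either fusion after adjustment (exact McNemar test, adjusted p 1 for all 19). The nearest was the endothelial list, with 2 genes listed for GFI1 alone and 9 for GFI1B alone (exact McNemar p 0.0654). By biotype, 79.5% of the GFI1 genes and 81.6% of the GFI1B genes were protein-coding, 2.13 percentage points more for GFI1B (Fisher's exact test, p 0.00592). Pseudogenes numbered 315 in the GFI1 list and 216 in the GFI1B list (odds ratio 1.51, Fisher's exact test, adjusted p 2.55e-05). Genes of small nucleolar RNAs numbered 84 and 56 (odds ratio 1.53, adjusted p 0.0407 by the same exact test over 6 biotypes). Large intergenic RNA genes, with 303 and 344, did not pass (exact adjusted p 0.273). These biotype tests treat the lists as separate, though the 2953 genes in both count on each side. With the shared genes left out the protein-coding difference was 4.98 percentage points, and the other biotypes were not tested that way.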

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

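The tests of long genes and of active genes below were chosen after the result was seen, and so were the comparison of receptors with other tandem families and the count of pseudogenes without chromosome X. Differences between the fusions compare 1 pooled list with another, and the tests of biotypes count genes in both lists on each side.

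Pseudogenes were listed more often for GFI1 than for GFI1B (odds ratio 1.51), and so were small nucleolar RNA genes (odds ratio 1.53), while the protein-coding share was 2.13 percentage points higher for GFI1B. Of the pseudogenes, 93 of 315 for GFI1 and 47 of 216 for GFI1B lay on chromosome X. That chromosome held 5.90% of all GFI1 genes and 4.52% of all GFI1B genes. Without it the odds ratio of pseudogenes was 1.37 (222 against 169 genes, Fisher's exact test, adjusted p 0.0139).

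Among 160 symbol families with at least 15 members, olfactory receptor genes (Olfr) were listed 42 times for GFI1 alone and 15 times for GFI1B alone (exact McNemar adjusted p 0.0368). Vomeronasal receptor genes (Vmn) were listed 28 times for GFI1 alone and never for GFI1B alone (exact McNemar adjusted p 1.19e-06). Counted by deposited symbol, both kinds together gave 77 genes for GFI1 alone and 17 for GFI1B alone. Weak intervals in the GFI1 list as the source are argued against. Its GFI1-only receptor genes (76 autosomal) had a median percentile of 72.9 by reads per kb among the autosomal genes of the list. A general excess of tandem gene families in the GFI1 list was not seen. The 19 other tandem families, picked by the start of the symbol, gave 22 genes for GFI1 alone and 21 for GFI1B alone. The rule set beforehand took no more GFI1-only than GFI1B-only genes as evidence against such an excess, and these counts just missed it. The receptors differed from these families (Fisher's exact p 0.000376), in a test added after the counts were seen. Counting 1 Mb bins in place of genes left 36 bins against 9 (exact McNemar p 6.57e-05). Reads shared between near-identical receptor copies stay open and untested. So do a calling threshold or control step that differed between the lists and a difference between the proteins. The tests of weak intervals and of tandem families looked for an excess in the GFI1 list. Against matched lists, given next, that list had no clear excess, so these tests leave a shortfall for GFI1B unaddressed. Relative to matched lists Vmn genes were fewer for GFI1B, with 6 of 355 Vmn genes against 29.2, while GFI1 had 34 against 33.4 (permutation adjusted p 0.0320 and 1). Olfr genes did not pass, with 25 of 1110 against 39.3 for GFI1B and 52 against 53.3 for GFI1 (permutation adjusted p 0.0960 and 1). The random lists drew genes independently. Neighbouring receptor genes may share intervals, so the p of the Vmn shortfall may be too small. That shortfall was not counted by 1 Mb bins.

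Genes of the endothelial, TGF-beta and adhesion lists were listed above matched lists for both fusions. Length of the gene itself as the whole source is argued against for the endothelial list and GFI1B. The permutation p among matched lists was 0.000200, the smallest they can give. This is the unadjusted value of the comparison given in Results, and no separate test. Matching did not cover the sequence between genes, from which intervals may be assigned at an unknown distance. The size of these surroundings as a source stays open and untested. Whether intervals were borrowed from a neighbouring gene could not be decided. Of the listed endothelial genes for GFI1B 3.85% lacked an interval of their own, meaning one listed under no other gene. Yet only 5.02% of all GFI1B intervals were listed under a further gene as well, so a low share would arise either way. The distance of assignment is not given, so an interval of a gene's own may still lie near a neighbour. Marking of active genes of any kind may contribute, because ribosomal protein genes exceeded their matched lists by more than endothelial genes did. For GFI1B they were listed 3.38 times as often as their matched lists, and endothelial genes 2.83 times. For GFI1 these ratios were 3.41 and 2.17. TGF-beta genes stood at 2.07 for GFI1 and 2.13 for GFI1B, and adhesion genes at 1.99 and 1.97. DAM reaches open chromatin by itself, and whether that share was removed stays open, as does binding by the fused proteins. Subtraction of control reads is stated for the GFI1B list and not known for the GFI1 list.

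Genes on chromosome X had fewer reads per kb than autosomal genes, 36.2 against 49.4 for GFI1 and 33.6 against 54.6 for GFI1B (permutation p 0.0001 for each, the smallest that 10000 permutations can give). Wider X intervals as the source are argued against. Median interval width was 1101 bp on X and 1201 bp on autosomes for GFI1, and 1401 and 1351 bp for GFI1B. The read number of genes with a single interval was lower on X as well, at 0.705 and 0.630 of the autosomal median. For GFI1 the narrower X intervals may lower that read number by themselves. A single copy of X in these cells is consistent with the ratios of reads per kb, 0.733 and 0.616, though the threshold of the interval calls hides weaker genes and the labels do not give the sex of the line. Of the 100 genes with the fewest reads per kb, 35 for GFI1 and 43 for GFI1B were on X. Of all listed genes 5.90% for GFI1 and 4.52% for GFI1B were on X. No biological explanation beyond copy number was tested.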

How the results depend on the processing

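Each group has 1 pooled sample of unknown depth, so the limits here are the deposited thresholds and the missing replicates. No paired analysis was possible because each group has 1 pooled sample. Filters on distance to the gene within 10 kb were not run, since the files give no distances. Strength by read number, shifts of intervals, lists matched on length and class, Ensembl identifiers and leaving out chromosome X were chosen after the data were seen.

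Sharing of genes, sharing of intervals, the rank relation and the protein-coding difference kept their direction and passed under each alternative run. For shared genes no alternative was matched on gene length, which both lists favour, so the range below does not cover that factor. The odds ratio of shared genes ranged from 13.4 (protein-coding background) to 44.9 (stronger 50% by read number), the excess of shared intervals from 13.4-fold (shifts) to 72.3-fold (stronger 50% by reads per kb), rho from 0.517 to 0.556, and the protein-coding difference from 2.13 to 4.98 percentage points.

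Taking the stronger 50% of genes shortened the lists by construction. Intervals are counted here once per gene they are listed under, 7462 for GFI1 and 8022 for GFI1B in full, against 7166 and 7595 distinct intervals. By reads per kb this left 2620 genes and 3757 such intervals for GFI1, and 2664 genes and 4125 for GFI1B. By read number it left 2635 genes and 4803, and 2675 genes and 5246. Fixed lists passing for GFI1 went from 15 to 9 with the protein-coding background, 8 with length-matched lists and 7 with lists matched on length and class. For GFI1B they went from 15 to 9 with the protein-coding background, 11 with length-matched lists and 8 with lists matched on length and class. The simulation, where Fisher's exact test against all genes called 48.9% of unchanged lists, shows gene length and class as a source of that loss. In the stronger 50% by reads per kb 3 lists for GFI1, 2 for GFI1B and 2 for both no longer passed, and 1 more passed for both. By read number 1 list for GFI1, 2 for GFI1B and 2 for both no longer passed, and 3 more passed for both. With chromosome X left out 1 for GFI1, 0 for GFI1B and 2 for both no longer passed.

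Some gene lists that did not pass, and a few that did, changed direction, and the cause was not tested beyond those backgrounds. With the protein-coding background the odds ratio was 0.921 for haematopoietic surface genes (GFI1B), 0.555 for erythroid genes (GFI1), and for megakaryocyte genes 0.741 (GFI1) and 0.706 (GFI1B). With lists matched on length and class the ratio of listed to expected genes was 0.881 for haematopoietic surface genes (GFI1B), 0.873 for erythroid genes (GFI1), 0.976 for megakaryocyte genes (GFI1B), 0.989 for LSD1 complex genes (both fusions) and 0.980 for Wnt genes (GFI1B). In the stronger 50% by reads per kb the odds ratio was 0.8001 for erythroid genes (GFI1) and 0 for haematopoietic surface genes (both fusions). By read number it was 0 for erythroid and for megakaryocyte genes (GFI1). In the stronger 50% by reads per kb the GFI1B-only minus GFI1-only count was -3 for TGF-beta and BMP genes and -1 for VEGF, PDGF and FGF genes, with adjusted p 1 for both (exact McNemar test).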

Other observations

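The comparisons in this part were chosen after the data were seen. Ubiquitin-conjugating and related genes (Ube) were listed for GFI1B 20 of 42 times against 9.69 in lists matched on length and class, and large ribosomal subunit genes (Rpl) 13 of 53 times for each fusion against 3.30 for GFI1 and 3.87 for GFI1B. These were the families above their matched lists among 160 tested in 3 classes (permutation adjusted p 0.0480 for Ube and 0.0320 for Rpl). Of the Ube genes 12 were listed for both fusions, 5 for GFI1 alone and 8 for GFI1B alone. The fusions were therefore not shown to differ in this family (exact McNemar p 0.581).

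Among genes listed for both fusions, no fixed list was shown to share intervals more or less often than other genes. All 17 endothelial genes listed for both, all 12 haematopoietic transcription factor genes and all 11 cardiac and smooth muscle genes had overlapping intervals of the fusions, against 77.5% of all 2953 shared genes. The same held for all 7 Wnt genes, all 6 ribosomal protein genes, all 5 arterial and Notch genes, all 3 pluripotency genes and the 1 erythroid gene. Long neuronal genes did so in 10 of 19 cases (52.6%) and adhesion genes in 15 of 23 (65.2%). Adjustment was over 18 lists (Fisher's exact test, smallest adjusted p 0.1997, for the endothelial and the long neuronal list, unadjusted p 0.0188 and 0.0222). Genes with more intervals have more chances of an overlap, and the test did not take this into account. The median interval number, in the fusion with fewer, was 2 for endothelial and 3 for haematopoietic transcription factor genes. It was 1 for cardiac and smooth muscle genes and for long neuronal genes, and 2 for adhesion genes.

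Hprt, the site where the fusions were inserted, was in neither list.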
